A study of Mus musculus with 2 samples.

How the data were processed

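Microglia were sorted from the brains of adult male C57BL/6J mice, an inbred laboratory strain, as cells positive for CD11b with low CD45, the usual gate that parts microglia from blood-derived myeloid cells. Per the labels' protocols, 3 mice received saline and are called awake here, and 3 mice received 100 mg/kg sodium pentobarbital, a barbiturate anesthetic. Brains were cut up, digested with collagenase and DNase, freed of myelin on a Percoll gradient and sorted, and cells were captured with the 10x Genomics Chromium 3' kit, which tags each RNA molecule with a unique molecular identifier (UMI) near its 3' end. Each group has 1 library. Whether the 3 mice of a group were pooled before capture, how long the anesthetic acted and at what time of day brains were taken are not given in the sources used here.

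The deposited files are 2 sparse matrices of UMI counts per gene and barcode, with their gene and barcode lists, and the values are whole-number counts, not normalized. Per the submitters' processing notes, reads were converted with bcl2fastq and counted with Cell Ranger 3.1.0 against the mouse genome GRCm38. Per the file headers, the matrices were written by Cell Ranger 4.0.0, and the difference between these versions could not be settled. The lowest deposited barcode held 501 UMIs. The authors' cell calling and any filter behind that floor are not described. The gene list names 55450 gene identifiers, and all 55450 matched the GENCODE M21 annotation of GRCm38, from which coordinates, transcript length and GC content were taken. The 217 symbols carried by more than 1 identifier were treated as separate rows.

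Cells were kept with at least 500 genes, at least 1000 UMIs and at most 10% of UMIs from mitochondrial genes. This left 8223 of 8600 awake and 8944 of 9412 anesthesia barcodes. Cells of both libraries were clustered together with scanpy 1.11.5 and leidenalg 0.10.2. Counts were scaled to 10000 per cell and log-transformed, and 2000 variable genes, 30 principal components, 15 neighbours and a Leiden resolution of 0.6 were used. Mitochondrial, ribosomal protein and hemoglobin genes, Gm42418, and the lists of immediate early genes, NF-kB and cytokine genes and heat shock genes were kept out of the variable genes. Clusters were named "X-like" from 10 markers for each of 15 cell classes fixed before the data were examined. A class other than microglia needed at least 3 of its markers among the 10 leading genes by fold and at least 3 markers seen in 25% of the cells. Microglia-like clusters needed 7 of 10 markers in 25% of the cells and at most 1 leading marker of any other class. Every cluster met the first condition, so the microglia-like name rested on the second. Clusters with a depth under 1/3 of their library and no leading marker of their own stayed unnamed. The 25% threshold was set after seeing the data. Scrublet called 0 awake and 1 anesthesia cell as doublets, 0.0112% of the anesthesia cells, so the caller did not work here and no cell was removed by it. An alternative left out the 8% of cells with the highest Scrublet scores in each library.

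UMI counts were summed per library over the microglia-like cells and scaled to a common total per library (CPM). The log2 ratio is anesthesia over awake, with the exact conditional binomial (Clopper-Pearson) 95% interval for 2 Poisson counts. CPM of single genes have exact Poisson and shares of cells exact Clopper-Pearson intervals. All these intervals cover counting error only. With 1 library per group there is no replicate, no test and no p-value, and cells were not used as replicates. Library, handling and group cannot be told apart. "Higher" and "lower" describe these 2 libraries.

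Genes with at least 200 UMIs over both libraries count as measured. For 24 gene lists fixed before the data were examined, the median log2 ratio of the measured members is given. Its 95% order-statistic interval describes the spread between members. Members at least 1.5-fold higher or lower were counted. The median's percentile among 10000 random lists matched on mean CPM in 20 bins describes where the list stood among the genes of these libraries. Named genes were the 12 with the largest and the 12 with the lowest log2 ratio among genes of at least 20 CPM in the higher library. Mitochondrial, ribosomal protein and hemoglobin genes, Gm42418, AY036118 and predicted models were left out of that rule. Up to 4 members with the largest differences per list and a few microglial genes were named as well. Genes outside these rules (Cirbp, Rbm3, Snhg6, Gas5, Malat1, Gm42418 and some list members) were chosen after their values were seen. Some list members are not reported here by name.

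Shares of cells with a UMI were computed after thinning each cell to 2000 UMIs, which left out 100 awake and 105 anesthesia microglia-like cells. The scripts were tested on simulated counts for 11834 genes, summed over all cells that pass the cell filter and not the microglia-like cells alone. Counts were Poisson draws from a common profile, without variation between mice or libraries. The values that follow therefore check the calculations and are no error rate for a design without replicates. All genes simulated at a log2 change of 1 or 2 in either direction were at least 1.5-fold apart in the right direction (100%), against 0.0429% of unchanged genes. The 95% intervals held the simulated ratio for 95.0% of genes, and 7% of 100 unchanged lists lay outside the 5th to 95th percentile.

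Alternatives planned before the data were examined were median-of-ratios scaling, all cells whatever their cluster, a stricter cell filter (1000 genes, 2000 UMIs, 5% mitochondrial), removal by Scrublet score, thinning, other count minimums, no cell filter and a Leiden resolution of 1.2. The comparison of lists within clusters was planned for clusters with at least 200 cells of each library. No microglia-like cluster reached that, so a minimum of 50 was used, chosen after seeing the data. Also chosen after seeing the data were removal of the trend with GC content and length (the median of each of 10 by 10 bins subtracted), removal of cells over 10000 UMIs, and a comparison within each microglia-like cluster pooled as a Mantel-Haenszel ratio, here called the within-cluster ratio. It is given as log2. The library with fewer UMIs in a cluster limits that cluster's weight. Small clusters shared by both libraries, such as clusters 6 and 7, therefore count for more than their share of cells. Other software was Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, igraph 0.11.9, anndata 0.12.19 and matplotlib 3.10.9.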

Results

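Single-cell RNA libraries of sorted brain microglia were compared between awake mice and mice given sodium pentobarbital, to ask how the RNA of microglia differs between the awake and the anesthetized state. There was 1 library per group, so no difference below has a replicate check, and every interval covers counting error only. The awake library held 53262885 UMIs in 8600 barcodes, with a median of 5883 UMIs and 2334 genes per barcode. The anesthesia library held 61139016 UMIs in 9412 barcodes, with a median of 5347 UMIs and 2152 genes. Its upper tail was deeper, with a 99th percentile of 29399 UMIs against 15803. The median share of mitochondrial UMIs was 1.45% in the awake and 2.26% in the anesthesia library.

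Microglia-like cells made up most of both libraries. They were 7312 of 8223 awake cells, 88.9% (95% interval 88.2 to 89.6), and 8065 of 8944 anesthesia cells, 90.2% (89.5 to 90.8). Choroid plexus or ependymal-like cells, led by Ttr and Enpp2, were 0.499% (0.358 to 0.676) of awake and 0.939% (0.750 to 1.16) of anesthesia cells. Neutrophil-like cells, led by S100a8 and S100a9, were 23 awake and 3 anesthesia cells, 0.280% (0.177 to 0.419) and 0.0335% (0.00692 to 0.0980). Endothelial-like cells were 1.37% and 1.38%, and border-associated macrophage-like cells 0.669% and 0.503%. Unnamed clusters held 8.26% of awake and 6.98% of anesthesia cells. The sort gate sets these shares, so they do not describe the brain.

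The microglia-like cells of the 2 libraries lay in different clusters. Clusters 1 and 3 held 4136 and 2607 awake cells but 116 and 105 anesthesia cells. Clusters 0 and 2 held 4296 and 3358 anesthesia cells but 81 and 102 awake cells. The comparisons below therefore set mainly clusters 1 and 3 of the awake library against clusters 0 and 2 of the anesthesia library, and a cluster that comes almost entirely from 1 library need not be a cell state. Summed over these cells, the awake library had 47516652 and the anesthesia library 55522359 UMIs, and 11369 genes were measured. Their median log2 ratio was -0.02, with the 5th percentile at -0.83 and the 95th at 0.93.

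Circadian clock genes were higher in the anesthesia library. The median log2 ratio of 18 measured members was 0.77 (0.28 to 1.04), above all 10000 matched random lists. Of these, 11 members were at least 1.5-fold higher and 0 lower. Per2, a repressor in the clock's feedback loop, had 85 UMIs (1.79 CPM, 1.43 to 2.21) in the awake and 680 (12.2 CPM, 11.3 to 13.2) in the anesthesia library, a log2 ratio of 2.78 (2.45 to 3.12). Cry1, its partner in that loop, had 1.47 (1.31 to 1.64). Nr1d1 and Nr1d2, the REV-ERB nuclear receptors that repress Arntl, had 1.34 (1.12 to 1.58) and 1.27 (1.19 to 1.35). The output factors Dbp, Tef and Hlf belong to the same list, and Dbp had 0.88 and Tef 0.70. Arntl, the activator that pairs with Clock, was at -0.34 (-0.54 to -0.15) and Nfil3 at -0.33, while Clock was at 0.71 and Per1 at 0.03 (-0.04 to 0.10). The within-cluster ratio gave the list a lower median of 0.41 and Per2 a log2 ratio of 3.36. That Per2 value rests on few UMIs and does not show a larger difference. Clusters 0 and 2 held 0 and 1 awake UMIs of Per2, and clusters 1 and 3 held 9 and 5 anesthesia UMIs. Cirbp, a cold-inducible RNA-binding protein, had 68.7 CPM in the awake and 205 CPM in the anesthesia library, a log2 ratio of 1.58 (1.52 to 1.63), and Rbm3, the other well-known cold-inducible RNA-binding protein, was at -0.35 (-0.38 to -0.32).

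**Figure D1:**
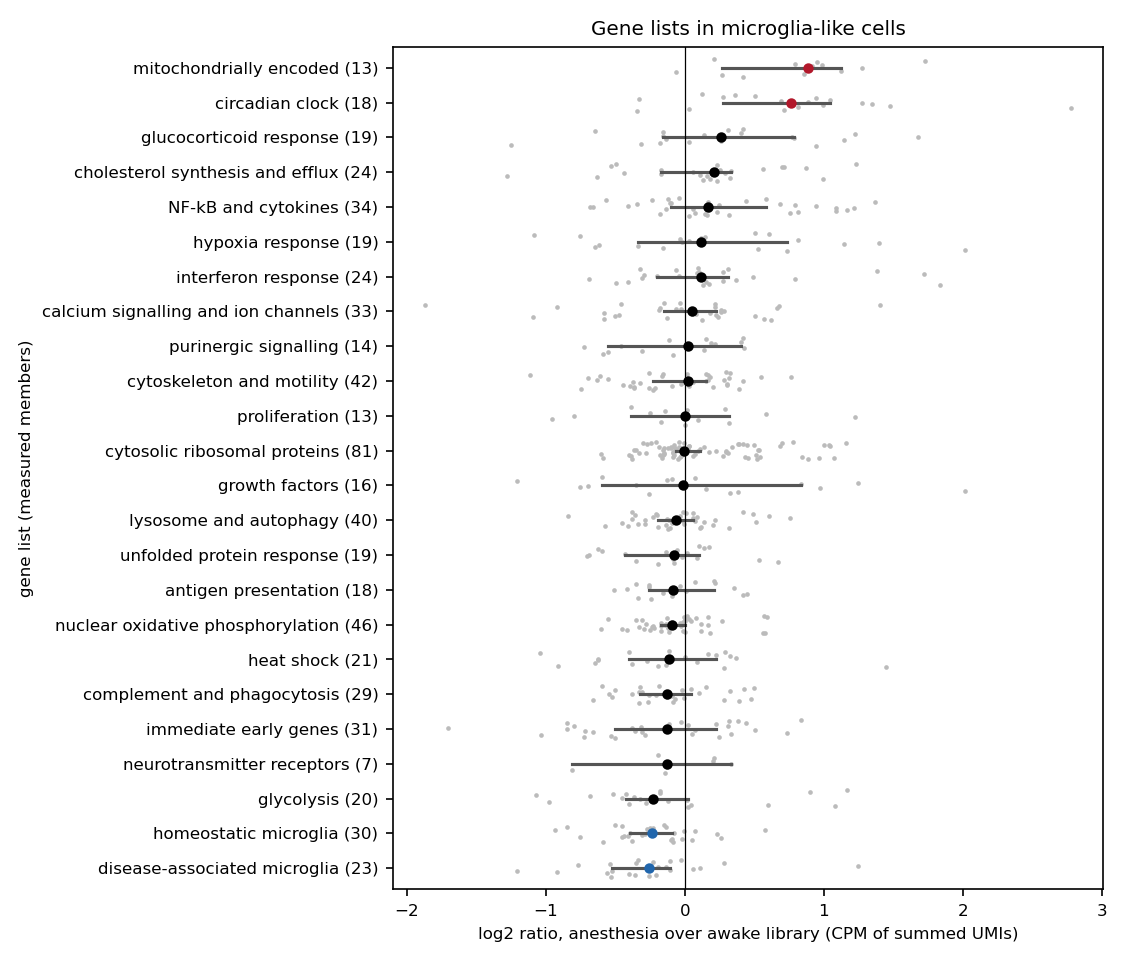
Log2 ratio of anesthesia over awake (x axis) for the measured members of 24 gene lists (grey points) in microglia-like cells, with the median of each list (large point) and its 95% order-statistic interval (bar). Red and blue medians have intervals above and below 0: clock (0.77) and mitochondrially encoded genes (0.88) lie above, homeostatic (-0.24) and disease-associated microglia genes (-0.26) below.

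Several cytokine and chemokine genes were higher in the anesthesia library. Of 34 measured NF-kB and cytokine genes, 11 were at least 1.5-fold higher and 2 lower, with a median log2 ratio of 0.16 (-0.10 to 0.59) at percentile 97.2 of random lists. Ptgs2, which encodes the inducible cyclooxygenase, was at 1.37 (1.24 to 1.497). Among the chemokines, Ccl4 had 2150 CPM in the awake and 5005 CPM in the anesthesia library, a log2 ratio of 1.22 (1.21 to 1.23), and Ccl3 was at 1.09 (1.08 to 1.10). The cytokine genes Il1b and Tnf were at 1.17 (1.11 to 1.22) and 1.09 (1.07 to 1.11). Nfkbia, the NF-kB inhibitor, was at 0.03, Il1a at 0.17 and Ccl2 at -0.14. The list median was 0.29 with the GC and length trend removed. By the within-cluster ratio the list median was -0.01, with 2 members higher and 3 lower. Ptgs2, Ccl4, Ccl3, Tnf and Il1b were then at 0.64, 0.47, 0.46, 0.54 and 0.25.

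Tnf, Ccl3 and Il1b were seen in more cells of the anesthesia library. With each cell thinned to 2000 UMIs, Tnf had a UMI in 42.2% (41.0 to 43.3) of awake and 66.2% (65.2 to 67.3) of anesthesia microglia-like cells. Ccl3 had one in 67.5% (66.4 to 68.6) and 94.4% (93.9 to 94.9), and Il1b in 7.35% (6.76 to 7.98) and 16.7% (15.9 to 17.5). Fos was seen in 84.1% of awake and 78.4% of anesthesia cells, and P2ry12 in 94.9% and 94.2%. Unthinned, Tnf was seen in 66.8% and 85.6%, Ccl3 in 82.7% and 98.3%, Il1b in 12.5% and 28.4%, Fos in 94.6% and 91.7%, and P2ry12 in 99.5% and 99.4%. Mki67, a marker of dividing cells, had a UMI in 5 of 7212 awake and 13 of 7960 anesthesia thinned cells, and in 20 and 29 cells unthinned. Endothelial-like cells, which should lack the microglial genes, gave thinned shares of 8.49% (9 of 106 cells) and 28 of 112 cells for Tnf, 24.5% and 51.8% for Ccl3, 0.943% and 10.7% for Il1b, and 21.7% and 36.6% for P2ry12. Fos, which endothelial cells also express, was seen in 82.1% and 83.0% of them, and Mki67 in 0 of 106 (up to 3.42%) and 0 of 112 (up to 3.24%). These shares were higher in the anesthesia library for each of Tnf, Ccl3, Il1b and P2ry12. Median depths were 5992 and 5503 UMIs for microglia-like and 5507 and 4535 UMIs for endothelial-like cells.

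Immediate early genes differed in both directions. Of 31 measured members, 8 were at least 1.5-fold lower and 2 higher, with a median of -0.13 (-0.50 to 0.22) at percentile 7.05. Klf2, a Krüppel-like factor that restrains inflammatory activation of myeloid cells, had 1082 CPM in the awake and 332 CPM in the anesthesia library, a log2 ratio of -1.71 (-1.73 to -1.68). Jund was at -1.04 (-1.05 to -1.02), Rhob at -0.85, Btg2 at -0.85, Jun at -0.53 and Fos at -0.50, while Egr1 was at 0.05. With the trend of GC content and length removed, the list median was 0.02 and Klf2 was at -1.33. The list median was -0.31 by the within-cluster ratio, with 8 members lower and 1 higher. The glucocorticoid response list had a median of 0.26 (-0.16 to 0.78), percentile 98.2, with 6 of 19 members higher and 2 lower. Its members split: the metallothionein gene Mt2 was at 1.67 (1.58 to 1.77) and Ddit4 at 1.14, and Fkbp5, a co-chaperone of the receptor, at 0.95, while Tsc22d3, which encodes the glucocorticoid-induced leucine zipper, was at -1.25 (-1.29 to -1.21). Mt2 and Tsc22d3 were at 0.91 and -0.55 by the within-cluster ratio.

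Homeostatic microglial genes were lower in the anesthesia library as a list. The median of 30 members was -0.24 (-0.39 to -0.09), percentile 0.130, with 4 members at least 1.5-fold lower and 0 higher. Bin1 was at -0.93 (-0.95 to -0.91), Gpr34, a lysophosphatidylserine receptor, at -0.76 (-0.78 to -0.74), and P2ry13, an ADP receptor, at -0.59 (-0.62 to -0.56). P2ry12, the ADP receptor that guides microglial processes, was at -0.08 (-0.10 to -0.07), Cx3cr1 at 0.05 (0.04 to 0.06), Csf1r at -0.10 and Tmem119 at -0.38 (-0.40 to -0.36). Cx3cr1 turned to -0.0345 with the GC and length trend removed. Tmem119 was at -0.0018 with that trend removed. Purinergic signalling genes had a median of 0.03 (-0.55 to 0.40), with 2 of 14 lower (P2ry13 and Adora3, an adenosine receptor, at -0.73) and 0 higher. With the GC and length trend removed 0 were lower. The 7 measured neurotransmitter receptor and transporter genes had a median of -0.13 (0.21 over the 30 members with at least 1 UMI in each library), with Gabbr1, a subunit of the GABA-B receptor, at -0.13 (-0.21 to -0.05) and Slc1a3, a glutamate transporter, at 0.21 (0.14 to 0.28). The list held 34 genes, and the GABA-A receptor subunits in it, on which barbiturates act, were under 200 UMIs and so not measured.

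Disease-associated microglia genes had a median of -0.26 (-0.52 to -0.11), percentile 0.855, with 3 of 23 members lower and 1 higher. Csf1 was the higher member, at 1.25 (1.15 to 1.34), and Spp1, Clec7a and Lgals3 were at -1.21 (-1.53 to -0.89), -0.92 (-1.08 to -0.77) and -0.77 (-1.01 to -0.53). A cluster led by such genes held 250 awake and 62 anesthesia cells. By the within-cluster ratio the list median was -0.05, and Csf1, Spp1, Clec7a and Lgals3 were at 0.08, -1.17, 0.0088 and 1.0002. The Spp1 value rests on few UMIs. Spp1 was at -4.44 in cluster 0, with 20 awake UMIs, and at -0.54 (-1.22 to 0.08) in cluster 6. Of 4 clusters with at least 20 UMIs of Spp1, 1 had an interval below 0. Complement and phagocytosis genes had a median of -0.13 (-0.32 to 0.04), with 2 of 29 lower (C5ar1 at -0.66 and Vav1 at -0.60), and 0 with the GC and length trend removed. C1qa was at -0.33. Antigen presentation genes had a median of -0.08 (-0.26 to 0.21), with 0 of 18 members beyond 1.5-fold in either direction. B2m was at 0.45 and Psmb8 at -0.51. Interferon response genes had a median of 0.11 (-0.20 to 0.31), percentile 86.7, with 4 of 24 higher and 1 lower. Ifit2 and Mx1 were at 1.84 (1.55 to 2.14) and 1.72 (1.504 to 1.95), from 2.504 and 4.46 CPM in the awake library, while Isg15 was at 0.18 and Irf7 at -0.31. The list median was 0.25 with the GC and length trend removed and -0.0077 by the within-cluster ratio, where Ifit2 and Mx1 were at 0.91 and 1.01.

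All but 1 of the genes encoded by mitochondrial DNA were higher in the anesthesia library. Their median was 0.88 (0.27 to 1.12), above all random lists, with 9 of 13 at least 1.5-fold higher and 0 lower, and it was 0.60 with the GC and length trend removed. Among them mt-Atp8, whose exons overlap those of a neighbour on the same strand, was at 1.73 (1.67 to 1.79) and mt-Nd6 at 1.27 (1.16 to 1.39). The 46 nuclear genes of oxidative phosphorylation had a median of -0.09 (-0.17 to 0.00044), with 1 higher (Cox6c, 0.59) and 1 lower (Ndufb10, -0.60). Gm42418, a locus that collects ribosomal RNA reads, was at 1.33 and Malat1, a nuclear RNA, at 0.32. Glycolysis genes had a median of -0.23 (-0.42 to 0.02), percentile 2.03, with 3 of 20 lower and 4 higher, or 2 and 0 by the within-cluster ratio. Eno1 and Pfkl were at -1.07 and -0.98, and Pfkfb3, which makes the activator of phosphofructokinase, at 1.16 (1.11 to 1.22), or 0.57 by the within-cluster ratio. The list median was -0.04 with the GC and length trend removed. Hypoxia response genes had a median of 0.12 (-0.33 to 0.74), with 6 of 19 higher and 4 lower. Vegfa went from 4.27 to 17.3 CPM (2.02, 1.80 to 2.24) and Adm was at 1.40, while Fam162a was at -1.08. Vegfa was at 1.02 by the within-cluster ratio. Cholesterol genes had a median of 0.21 (-0.17 to 0.33), percentile 96.6, with 5 of 24 higher (Mylip, 1.23, and Insig1, 0.99) and 2 lower (among them Fdps, -1.28). Cytosolic ribosomal protein genes had a median of -0.01 (-0.06 to 0.11) with 11 of 81 higher and 2 lower, led by Rps28 (1.16) and Rps21 (1.07). With the GC and length trend removed that median was 0.20, with 19 higher and 0 lower. Lysosome and autophagy genes had a median of -0.06 (-0.19 to 0.06), with 2 of 40 higher (Atp6v1a, 0.76, and Sqstm1, 0.60) and 1 lower (Tfeb, a regulator of lysosomal genes, -0.84). None was higher by the within-cluster ratio.

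Heat shock genes had a median of -0.12 (-0.40 to 0.23), with 5 of 21 lower and 1 higher. The percentile of this list went from 13.9 to 0.340 and its median to -0.22 with the GC and length trend removed. Hspa8, a constitutive chaperone, was at -0.91 and Chordc1 at -1.04, while the inducible Hspa1b was at 1.44 (1.36 to 1.53). Unfolded protein response genes had a median of -0.08 (-0.43 to 0.10), with 4 of 19 lower (Sdf2l1, -0.71, and Calr, -0.62) and 1 higher (Atf6, 0.67). With the GC and length trend removed 0 were lower and 0 higher. Calcium signalling and ion channel genes had a median of 0.05 (-0.15 to 0.22), with 4 of 33 higher and 3 lower. The calcium-activated potassium channel Kcnn4 was at -1.87 (-2.32 to -1.43), from 181 and 58 UMIs, and the inward rectifier Kcnj2 at 1.41 (1.196 to 1.62). Cytoskeleton and motility genes had a median of 0.02 (-0.23 to 0.15), with 5 of 42 lower (Tuba1a, -1.12, and Actg1, -0.75) and 1 higher (Ezr, 0.76). Growth factor genes had a median of -0.01 (-0.59 to 0.84), with 4 of 16 higher, among them Vegfa and Hbegf (0.97), and 4 lower, or 1 and 2 by the within-cluster ratio. Proliferation genes had a median of 0.0036 (-0.39 to 0.32), with 2 of 13 higher (Hmgb2, 1.22, and Mcm2, 0.59) and 2 lower (Cenpf, -0.95, and Tyms, -0.79). By the within-cluster ratio Ezr, Hbegf and Mcm2 were at 0.12, 0.08 and -0.19 and the proliferation list at -0.48, with 1 member higher and 5 lower. Cenpf was at -1.85 without cells over 10000 UMIs.

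Of the 12 genes highest in the anesthesia library by the fixed rule, Cd27, a receptor of the TNF receptor family (chromosome 6, 125232622 to 125237010, GRCm38), was 4.44-fold higher, with 389 and 2020 UMIs and a log2 ratio of 2.15 (1.99 to 2.31). Vamp1, a SNARE protein gene whose span on the other strand (chromosome 6, 125215551 to 125245964) contains Cd27, was at 1.74. Zc3h6 (chromosome 2, 128967402 to 129018563) was at 2.09 (1.91 to 2.27) and Caprin2, which encodes an RNA-binding protein, at 1.96. Tmem71 (1.87), Mir155hg (1.86), the Ral activator Ralgds (1.83), the TNF ligand family gene Tnfsf9 (1.77), the DNA-binding factor Arid3a (1.75), the orphan nuclear receptor Nr4a3 (1.74), Mt2 (1.67) and Csrnp2 (1.66) completed the group. By the within-cluster ratio Tnfsf9 and Nr4a3 were at 0.43 and 0.58, Csrnp2 at 1.05, Caprin2 at 1.09 and Mir155hg at 1.12.

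The 12 lowest genes were led by the histone gene Hist3h2a (chromosome 11, 58954685 to 58956830), with 1526 and 472 UMIs and a log2 ratio of -1.92 (-2.07 to -1.77), and by Klf2 (chromosome 8, 72319033 to 72321656). Srxn1, which encodes sulfiredoxin of the oxidative stress response, was at -1.68 (-1.85 to -1.51). The mitochondrial proteins Coa3, a cytochrome c oxidase assembly factor, Mrpl14, of the mitochondrial ribosome, and Mtg2, a GTPase, were at -1.52, -1.52 and -1.36. Fam219b (-1.46), Fbxw4 (-1.40), Snapc5 (-1.36), the stress gene Nupr1 (-1.32), Tmem273 (-1.30) and the arginine methyltransferase Prmt2 (-1.30) made up the rest. Same-strand exons of another gene overlap 3 of the 12 highest (Cd27, Zc3h6 and Mir155hg) and 2 of the 12 lowest (Hist3h2a and Prmt2), and their counts are uncertain for that reason. Near-identical copies make Hspa1b and the ribosomal protein genes uncertain in the same way. Mir155hg, Nr4a3, Tnfsf9, Csrnp2, Vegfa, Klf2, Tsc22d3, Hist3h2a and Srxn1 were also leading genes of clusters that came almost entirely from a single library.

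**Figure D2:**
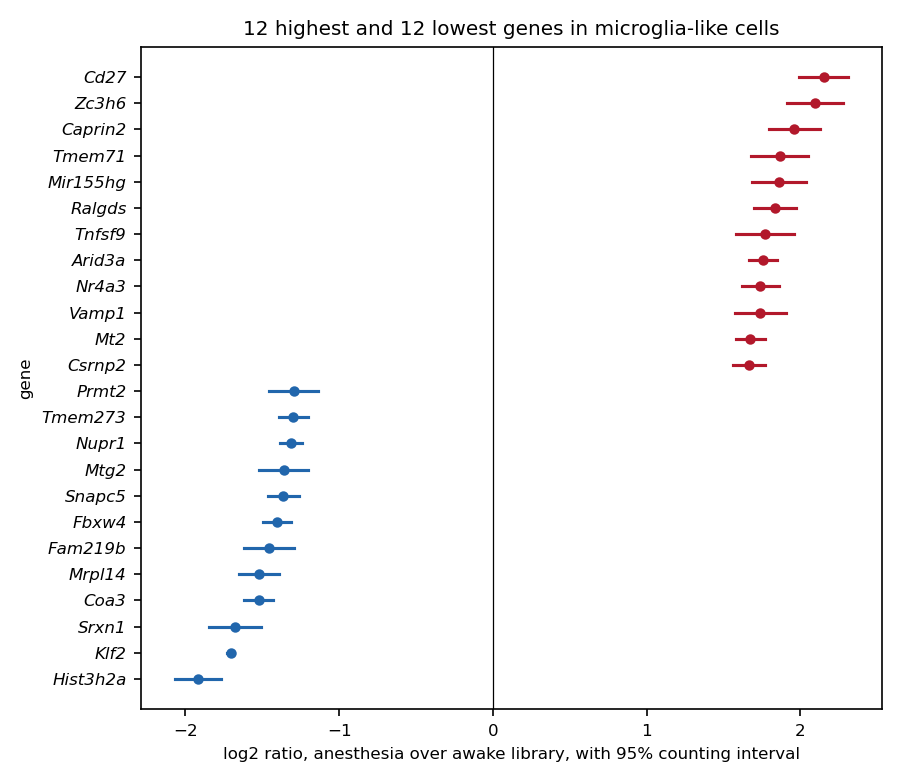
Log2 ratio of anesthesia over awake (x axis) of the 12 highest (red) and 12 lowest (blue) genes in microglia-like cells, with exact 95% counting intervals (bars), 1 library per group. The values run from 2.15 for Cd27 to -1.92 for Hist3h2a.

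The direction within clusters was shared for some genes and mixed for others. Of 6 microglia-like clusters with at least 50 cells of each library, Cirbp was higher in the anesthesia cells of 6 (1.30 to 2.18) and Nr1d2 higher in 6 (0.44 to 1.93). The clock list had enough measured members in 4 clusters, and its median was above 0 in 4, from 0.11 to 0.71. Klf2, Tsc22d3, Fos and Jund were lower in 6 of 6, with all 6 counting intervals below 0. Tnf was higher in 6 (0.23 to 0.99) with 6 intervals above 0. Ccl3 was higher in 5 with 1 opposite (-0.09 to 1.25), and Il1b higher in 4 and lower in 2 (-0.49 to 0.67). Nr1d1 was higher in 4 and lower in 1 of 5 clusters with enough UMIs, Vegfa higher in 5 of 5, and Csf1 higher in 4 and lower in 2, each with 1 interval above 0. Clec7a was higher in 3 and lower in 3, with 2 intervals below 0, and the NF-kB and cytokine list above 0 in 3 and below in 3. The homeostatic list was below 0 in 6 clusters (-0.49 to -0.06), the immediate early list below 0 in 6 (-0.47 to -0.28), and the mitochondrially encoded list above 0 in 6 (0.26 to 1.21). In the 4 largest clusters, 1 of the libraries gave only 81 to 116 cells, which were assigned there because they resembled the other library.

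**Figure D3:**
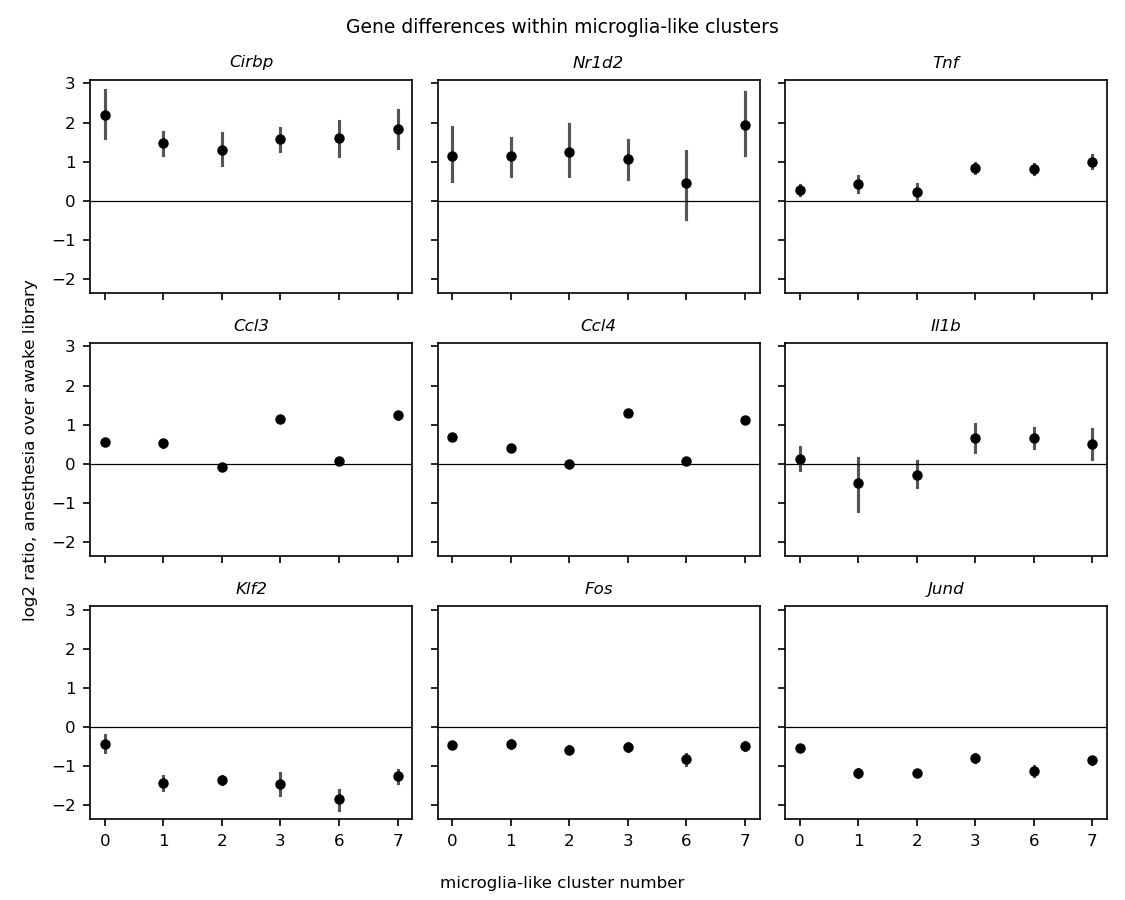
Log2 ratio of anesthesia over awake (y axis) of 9 genes in each of 6 microglia-like clusters (x axis, cluster number), with exact 95% counting intervals (bars, often hidden by the points). Cirbp lies between 1.30 and 2.18 and Klf2 between -1.85 and -0.42, while Ccl3 and Il1b lie on both sides of 0.

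The ratios also followed properties of the transcripts. Across the 11369 measured genes, which are not independent replicates, the Spearman correlation of the log2 ratio with transcript GC content was -0.26 and with transcript length 0.25. The tenth of genes with the lowest GC content had a median log2 ratio of 0.25 and the tenth with the highest -0.20. The tenth with the longest transcripts had a median of 0.26. Median-of-ratios scaling shifted every log2 ratio by 0.017. Markers of other cell types were low in the microglia-like sums. The neutrophil gene S100a8 had 14.7 CPM in the awake and 1.19 CPM in the anesthesia library, and the hemoglobin gene Hbb-bs 18.0 and 43.1 CPM. Sums of 10 markers were 19.3 and 23.6 CPM for neurons, 83.8 and 93.5 CPM for astrocytes, of which Slc1a3 alone gave 65.2 and 75.4 CPM, and 131 and 123 CPM for oligodendrocytes, against 20557 and 18373 CPM for the microglial markers. Larger sums were 236 and 165 CPM for neutrophils, 236 and 208 CPM for B cells, and 134 and 134 CPM for border-associated macrophages. Most of these came from Csf3r (184 and 161 CPM), Ighm (195 and 180 CPM) and Stab1 (121 and 120 CPM).

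**Figure D4:**
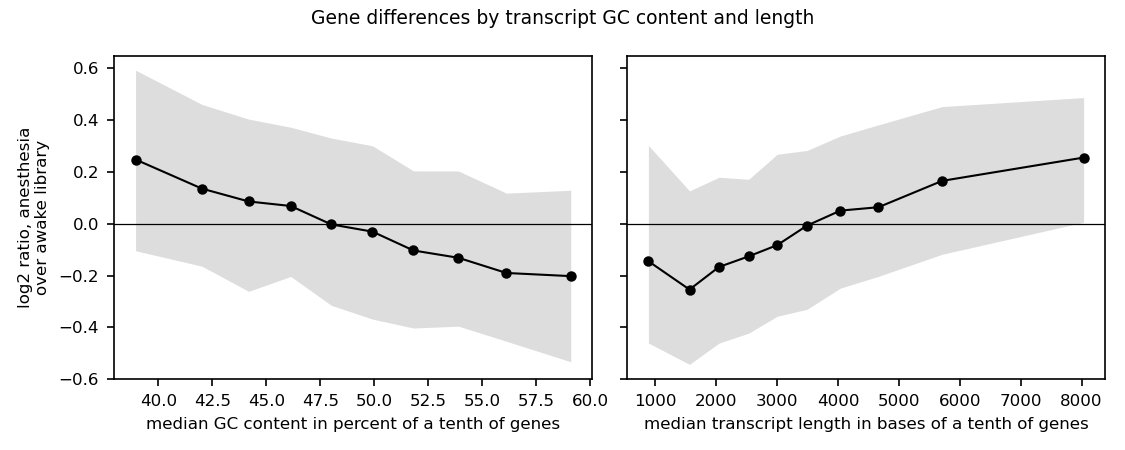
Median log2 ratio of anesthesia over awake (y axis, points) in 10 equal groups of the 11369 measured genes by transcript GC content in percent (left) and transcript length in bases (right), with the 25th to 75th percentile of genes shaded. The median goes from 0.25 in the tenth with the lowest GC content to -0.20 in the tenth with the highest.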

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

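The tests on clock genes and on Ccl3, Ccl4 and Tnf below were chosen after the results were seen, and the 2 tests of the trend with GC content were written before their results were seen.

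The 24 named genes were compared between the libraries in microglia-like cells, and cells of 3 other classes showed the same direction for most of those with enough UMIs. In endothelial-like cells (113 awake, 123 anesthesia), 17 of the 19 genes with at least 20 UMIs went the same way as in microglia-like cells, 13 of them with a counting interval that excludes 0. In border-associated macrophage-like cells (55 and 45) it was 19 of 20, with 14 such intervals, and in choroid plexus or ependymal-like cells (41 and 84) 7 of 8, with 4. No interval excluded 0 in the opposite direction among the genes with at least 20 UMIs. These cells also held microglial RNA, and free RNA and doublets with microglia were not separated as its source. P2ry12 reached 15.9% of its microglial level in the awake and 38.8% in the anesthesia endothelial-like cells, and 44.6% and 86.6% in the macrophage-like cells, whose median depth was 6400 and 10930 UMIs. Of the genes counted, 11, 6 and 3 also exceeded 2 times that level in the endothelial-like, macrophage-like and choroid-like cells. The level was taken from the library where the gene was higher. In macrophage-like cells all 6 were genes lower in the anesthesia library, judged against 44.6%. For the higher genes, 2 times 86.6% lies above the full microglial level. The share of P2ry12 was higher in the anesthesia library in all 3 classes. Microglial RNA alone can therefore give genes higher in that library the same direction in these classes. Among the genes that passed, Snapc5 was at -1.03 (-1.64 to -0.43) in endothelial-like and at -1.46 (-2.55 to -0.41) in macrophage-like cells.

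Clock genes were higher in the anesthesia library (median log2 ratio 0.77). The tables argue against the trend with GC content and length as the cause, since the median was 0.79 (0.28 to 1.19) once it was removed. Compared within clusters and pooled, the median was 0.41 (0.19 to 1.03), so the clusters as drawn do not account for the whole difference. How much they account for cannot be told. The largest clusters came almost entirely from a single library, and their few other cells were placed there because they resembled it. Time of day of collection cannot be told apart from the group, because the labels give no collection time. Arntl, which cycles in opposite phase to the Per and Nr1d genes, was at -0.34, the direction a shift of phase would give. Per1, however, was at 0.03 (-0.04 to 0.10) although Per2 was at 2.78, and Clock, the partner of Arntl, was at 0.71. An effect of pentobarbital on the clock or on body temperature stays open and untested.

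Ccl3, Ccl4 and Tnf were each about 2-fold higher in the anesthesia library (log2 ratios of 1.09, 1.22 and 1.09). The GC and length trend is argued against, since the lowest of the 3 was at 1.10 once it was removed. Compared within clusters and pooled, the lowest was at 0.46, so the clusters as drawn do not account for the whole difference. All 3 intervals lay above 0 in 5 of 6 clusters. Ccl3 and Ccl4 were both at only 0.08 in cluster 6. In cluster 2, with 3358 anesthesia cells, they were at -0.09 and 0.0064. How much the clusters account for cannot be told, because the largest came almost entirely from a single library. Activation during dissociation and sorting cannot be told apart from the treatment, because each group was handled as 1 library. The immediate early genes, which such handling induces as well, had a median of -0.13 (-0.31 by the within-cluster ratio) with members in both directions, and that does not decide it.

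Long, GC-poor transcripts were higher in the anesthesia library. The correlation with GC content was -0.26 both before and after every cell was thinned to 2000 UMIs. The weight of deep cells in the sums therefore does not account for it. Thinning draws UMIs at random, so it cannot decide on a depth-related bias already present in the counts of each cell. A library-wide difference in RNA or library preparation could not be settled. In endothelial-like cells, over 955 genes at least 4-fold higher there than in microglia-like cells, the correlation with GC content was -0.076, against -0.22 in microglia-like sums thinned to the same UMIs, and for the GC content of the last part of the transcript -0.13 against -0.25, while the correlation with length was 0.20 against 0.29. No biological explanation of this trend was tested.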

How the results depend on the processing

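Removal of the GC and length trend, the within-cluster ratio and removal of cells over 10000 UMIs were chosen after seeing the data; the other settings were planned. The 24 list medians were recomputed under 10 settings, and 235 of 240 values stayed within the main order-statistic interval. That interval describes the spread between members and is often wide, so staying within it does not show a stable median. The NF-kB and cytokine median stayed within it while going from 0.16 to -0.01 by the within-cluster ratio. In 11 lists the sign was the same in all 10: the clock list ranged from 0.41 to 0.85, the mitochondrially encoded list from 0.60 to 0.92, and the homeostatic list from -0.30 to -0.14. With the GC and length trend removed, nuclear oxidative phosphorylation moved to 0.0383 and ribosomal proteins to 0.2013, and growth factors were at 0.19, cholesterol at 0.12, purinergic at 0.07, antigen presentation at 0.05, lysosome at 0.02, cytoskeleton at -0.0038, unfolded protein response at -0.03, complement at -0.05, neurotransmitter at -0.07, homeostatic at -0.14 and disease-associated at -0.16. By the within-cluster ratio, disease-associated microglia genes moved to -0.0461, nuclear oxidative phosphorylation to 0.0609 and proliferation to -0.4822, and hypoxia was at 0.24, ribosomal proteins at 0.08, cytoskeleton at 0.05, purinergic at -0.03, calcium at -0.04, neurotransmitter at -0.06 and unfolded protein response at -0.18. The within-cluster ratio takes out the sizes of clusters, among them the cluster led by disease-associated genes, with 250 awake and 62 anesthesia cells. Whether cluster sizes account for the move of the disease-associated list was not tested. Of 117 single genes under 8 settings, 112 kept their sign throughout, but their sizes often moved. Of 936 values, 675 stayed within the main counting interval, 255 moved outside it and 6 reversed. With the GC and length trend removed 84 of the 117 genes moved, and by the within-cluster ratio 82. Reversed were Clec7a (0.0088), Lgals3 (1.0002) and Mcm2 (-0.19) by the within-cluster ratio, and Cx3cr1 with cells thinned to 2000 UMIs (-0.0023), with the trend removed (-0.0345) and without cells over 10000 UMIs (-0.0025). Slc1a2, whose main counting interval included 0, changed sign with all cells that pass the filter (-0.2969) and with the trend removed (-0.0737). The neurotransmitter list turned from -0.13 to 0.2076 when 1 UMI in each library was enough, with 30 members in place of 7. Counts of members at least 1.5-fold apart that moved by more than 1.5 times under at least 1 of the 10 settings are given as the main count and its range, except 1 count that is not given. Higher: NF-kB and cytokines 11 (2 to 12), clock 11 (7 to 12), ribosomal proteins 11 (11 to 19), glycolysis 4 (0 to 4), growth factors 4 (1 to 5), calcium 4 (1 to 5), immediate early 2 (1 to 5), proliferation 2 (1 to 4), lysosome 2 (0 to 2), nuclear oxidative phosphorylation 1 (1 to 3), unfolded protein response 1 (0 to 2), cytoskeleton 1 (0 to 1), neurotransmitter 0 (0 to 11), purinergic 0 (0 to 2), homeostatic 0 (0 to 1) and antigen presentation 0 (0 to 1). Lower: cytoskeleton 5 (3 to 6), unfolded protein response 4 (0 to 5), growth factors 4 (2 to 5), hypoxia 4 (2 to 4), disease-associated 3 (1 to 7), calcium 3 (2 to 5), purinergic 2 (0 to 3), complement 2 (0 to 4), proliferation 2 (0 to 5), cholesterol 2 (0 to 3), glucocorticoid 2 (1 to 2), ribosomal proteins 2 (0 to 2), interferon 1 (0 to 5), nuclear oxidative phosphorylation 1 (0 to 1) and clock 0 (0 to 1). The microglia-like share moved to 82.9% of awake and 83.9% of anesthesia barcodes with no cell filter, to 92.7% and 96.4% with the stricter filter, and to 87.9% of awake cells at a Leiden resolution of 1.2. Unnamed clusters held 13.3% and 12.1% with no cell filter and 5.16% and 1.57% with the stricter filter, which also left 0.2625% and 0.5112% choroid plexus or ependymal-like cells. The causes of these moves were not tested. All 12 thinned shares of cells with a UMI moved without thinning, as depth sets them. Depth limits genes of few UMIs such as Per2 (85 awake UMIs) and Kcnn4 (58 anesthesia UMIs). The missing replicates limit every value. No paired analysis was possible because each group has 1 library.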

Other observations

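Some host genes of small nucleolar RNAs were noticed in the data. They were not a fixed list, no random lists were drawn for them, and Zfas1 is also on the hypoxia list. Snhg6, Snhg12 and Zfas1 were among the leading genes of cluster 2, which held 102 awake and 3358 anesthesia cells. Of 12 measured genes chosen by name (those named Snhg with a number, Gas5 and Zfas1), 6 were at least 1.5-fold higher and 0 lower, 11 counting intervals lay above 0, and the median log2 ratio was 0.55. That median was 0.62 with the GC and length trend removed and 0.50 by the within-cluster ratio. Snhg6 had 20.6 CPM in the awake and 50.4 CPM in the anesthesia library (log2 ratio 1.29, 1.19 to 1.40), Zfas1 142.9 and 217.3 CPM (0.60) and Gas5 434.7 and 547.4 CPM (0.33).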
